A study of Homo sapiens with 4 samples.

How the data were processed

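Chromatin accessibility was measured by ATAC-seq, in which a transposase (Tn5) inserts sequencing adapters into open DNA, in 4 libraries of SUM159, an established mammary carcinoma cell line. By their titles, 2 libraries were low and 2 were high in ITGB4 (given there under its CD name), called ITGB4-low and ITGB4-high sublines here. Each library's replicate number was also taken from its title. Nothing in the labels says whether the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

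Peaks were called in each library on its own with MACS 2.1.1.20160309, without a control and with a p cutoff of 0.01, per the file headers. Per the file headers, tags were shifted and extended to 150 bp around the transposase insertion and the input carried no further duplicate removal by the caller. The genome build was hg19, per the submitters' processing notes, and the aligner is not given in the sources used here. For each library the authors deposited an unfiltered peak table and a shorter list filtered by IDR (irreproducible discovery rate), and for the ITGB4-high libraries also a naive-overlap list. The IDR procedure is not given in the sources used here, and the list of ITGB4-low replicate 2 carries a slightly different name from the other 3, so it may have been made in another run.

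The pileup in the deposited tables is a signal: the coverage at a peak's summit by extended Tn5 ends, which was a whole number in 100% of rows and was not scaled to depth. The deposited significance of a peak is the −log10 of the caller's p-value and of its q-value. The deposited fold enrichment is the ratio of the pileup to the caller's local background, each with 1 added. The deposited filtered lists also hold a score per peak, which entered no test. These peak values are the authors' own and were used to rank or filter peaks within a list. The local background was recovered from pileup and fold enrichment. It is the larger of the genome mean and the mean over 10 kb, so it never falls below the genome mean, and a difference is understated where a library is at that floor. It includes the tags of the peak itself, so a difference can also be inflated where peaks differ. In bins of 10 Mb, background away from the regions was the upper quartile over the unfiltered peaks there, not their median. In windows of 1 Mb and 500 kb it was the median.

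Depth was 30560426 and 18822664 tags in ITGB4-high replicates 1 and 2, and 21049644 and 27160312 in ITGB4-low replicates 1 and 2, per the file headers. The unfiltered tables held 211700, 186055, 218915 and 193371 summits in the same order.

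Filtered peaks of the 4 libraries on chromosomes 1 to 22 and X were merged where they overlapped by 1 bp or more, which gave 44075 regions. A region was group-specific when it overlapped a filtered peak in both libraries of 1 group and in neither of the other. A missing peak is a call below a list's threshold and not closed chromatin. Similarity of libraries was the Jaccard index in bp. Shares of group-specific regions per chromosome were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 23 chromosomes. These tests count regions, which are not independent replicates.

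The summit pileup test used the highest pileup per region and library on a log2 scale, without a pseudocount, in the 35884 regions (81.4%) with a peak in the unfiltered tables of all 4 libraries. Pileups quoted per region were scaled to 1000000 tags, while for the test each library was centred on its median, and limma compared 2 libraries with 2, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pileup is not a count of fragments, so no count model was used. On simulated data for this comparison over 35884 regions, with 4000 changed, the test called 37.4% of 2-fold and 98.5% of 4-fold changes, and 2.79% of its calls were false. With 200 changed it called 0% of 2-fold and 57% of 4-fold changes.

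Regions were named by rules fixed before the data were examined: in each direction the 8 group-specific regions with the highest mean percentile of the caller's p, and the 6 regions with the largest fold changes among those with adjusted p under 0.05 and no overlap between the groups. A few 500 kb windows, 1 Mb windows and stretches were chosen after their values were seen, and the text says so. Alternatives were a stricter caller threshold, lists of equal length, absence from longer lists, another overlap rule, other scalings, filling of missing pileups, a filter on low pileups, the replicate number as a block and leaving out each library. Centring within 10 Mb bins, division by local background and leaving out chromosomes 3, 11 and 18 were added after the data were seen. Only 3 splits of 4 libraries into pairs exist, so no test over splits can reach 0.05.

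Gene annotation and genome sequence of hg19 were not used here, and coordinates were not converted between builds. Regions are given by hg19 position without gene names, and the planned comparisons of gene lists, transcription factor motifs and promoter shares were not run. R 4.3.3 with limma 3.58.1 was used for the test, and Python with pandas and SciPy for overlaps and Fisher's exact tests.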

Results

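Open chromatin was profiled by ATAC-seq in 2 sublines of SUM159 mammary carcinoma cells that carry low or high levels of ITGB4, an integrin subunit that binds laminin, with 2 libraries per subline. The comparison asks where chromatin accessibility differs between the sublines. The IDR-filtered lists held 22453 and 18177 peaks in ITGB4-high replicates 1 and 2, covering 13.6 and 9.95 Mb. In ITGB4-low replicates 1 and 2 they held 28767 and 36722 peaks, covering 16.8 and 21.4 Mb. The deepest library, ITGB4-high replicate 1 with 30560426 tags, had fewer filtered peaks than both ITGB4-low libraries.

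Libraries of the same subline shared more of their open chromatin than libraries of different sublines. The Jaccard index of filtered peaks was 0.503 for the ITGB4-high pair and 0.545 for the ITGB4-low pair, and lay between 0.347 and 0.438 for the 4 pairs across sublines. With the 18177 most significant peaks of each library, the within-subline values were 0.522 and 0.578 and the others lay between 0.422 and 0.462. Across the 35884 regions with a peak in every unfiltered table, Pearson correlations of log2 pileup were 0.86 and 0.87 within sublines and 0.64 to 0.65 between them. These correlations are across regions, which are not independent replicates.

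Of 44075 regions, 11709 (26.6%) had a filtered peak in all 4 libraries, 1140 were specific to ITGB4-high and 7079 to ITGB4-low. Among the ITGB4-high-specific regions with the most significant peaks was chromosome 3, 166161884 to 166163019, with depth-scaled summit pileups (per 1000000 tags) of 5.92 and 6.16 in ITGB4-high and a peak of 0.475 in only 1 ITGB4-low library. The region on chromosome 12, 107908864 to 107909818, reached scaled pileups of 4.68 and 4.83 in ITGB4-high and was listed in neither unfiltered ITGB4-low table. The other regions in this set were on chromosome 8 at 128438900, chromosome 5 at 116099514, chromosome 1 at 183167439 and 5711886, and chromosome 2 at 217548413 and 84077835 (start positions).

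The leading ITGB4-low-specific region was chromosome 6, 119861993 to 119862945, with scaled pileups of 5.08 and 6.11 in ITGB4-low against 1.15 and 1.01 in ITGB4-high. Chromosome 11, 122085843 to 122086445, had scaled pileups of 6.08 and 5.15 in ITGB4-low against 0.654 and 0.691 in ITGB4-high. The set also held chromosome 5 at 109624230 and 97966938, chromosome 8 at 128342240, chromosome 9 at 101751474, and chromosome 11 at 119351756 and 121955766. On chromosome 8, the ITGB4-high-specific region at 128438900 and the ITGB4-low-specific region at 128342240 thus lay in the same 1 Mb. In the summit pileup test, the regions on chromosome 6 at 119861993 and chromosome 11 at 122085843 had log2 differences of -1.92 and -2.60. After division by the local background these were -0.51 and -0.75 and no longer passed the threshold (limma, Benjamini-Hochberg adjusted p = 0.288 and 0.152). The ITGB4-low-specific regions at 101751474, 121955766 and 97966938 and the ITGB4-high-specific region at 183167439 also lost the threshold in that setting.

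Most group-specific regions also had an unfiltered peak in the other subline. An unfiltered peak in at least 1 library of the other subline was found for 84.8% of ITGB4-high-specific and 94.5% of ITGB4-low-specific regions. Requiring absence from the unfiltered tables left 173 and 386 regions. Requiring absence from the naive-overlap lists, which were given only for ITGB4-high, left 1929 of the 7079 ITGB4-low-specific regions. With lists of equal length the counts were 2242 ITGB4-high-specific and 2478 ITGB4-low-specific regions, and equal lengths by themselves bring these counts close together. Without ITGB4-high replicate 1 the counts were 2085 and 10641, without ITGB4-high replicate 2 they were 3267 and 8497, without ITGB4-low replicate 1 they were 1525 and 15993, and without ITGB4-low replicate 2 they were 2293 and 10135, because fewer libraries then had to meet the criteria. The subline split gave 8219 specific regions, against 995 when replicates 1 were set against replicates 2 and 1592 when the libraries were crossed.

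**Figure D1:**
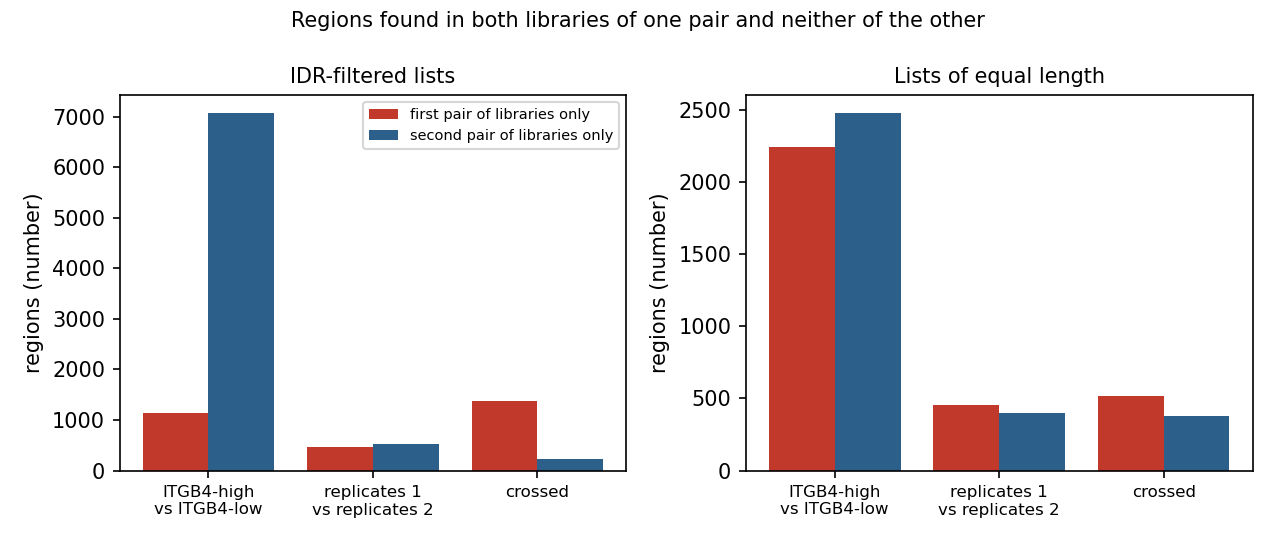
Bars give the number of regions with a filtered peak in both libraries of a pair and in neither of the other pair, for the 3 ways of splitting the 4 libraries, with the deposited filtered lists (left) and with lists of equal length (right). In each split the first-named pair is red and the other blue, and the subline split gave the most regions in both panels, 8219 and 4720.

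In the summit pileup test, 2347 regions were higher and 2170 lower in ITGB4-high (limma, Benjamini-Hochberg adjusted p under the threshold), which is 12.6% of the 35884 tested, and the median standard error of a log2 difference was 0.28. Differences of at least 4-fold were found for 289 of the higher and 121 of the lower regions. The largest increases were on chromosome 6, 8627704 to 8628218, with a log2 difference of 3.78 ± 0.42 (SE, n = 2 per subline, limma adjusted p = 0.00201), and on chromosome 1, 15059278 to 15060302, with 3.59 ± 0.28 (adjusted p = 0.00167). The depth-scaled pileup of the chromosome 6 region was 3.98 ± 0.451 in ITGB4-high and 0.450 ± 0.301 in ITGB4-low (SD, n = 2). After division by the local background, which includes the peak's own tags, the log2 difference of this region was 1.76 and no longer passed the threshold (limma, Benjamini-Hochberg adjusted p = 0.0746). The other 4 were on chromosome 3 at 174529998, chromosome 6 at 18353089, chromosome 1 at 55047173 and chromosome 11 at 45757846, with log2 differences of 3.58, 3.43, 3.41 and 3.35. Their unscaled ITGB4-low pileups were 5 to 8, near the lowest unfiltered pileups of those libraries, 4 and 5. After division by the local background the log2 differences of these 4 were 1.72, 2.09, 2.03 and 1.71 (limma, Benjamini-Hochberg adjusted p = 0.0478 to 0.0493). The chromosome 1 region at 15059278 also had low ITGB4-low pileups, 5 and 7, and the chromosome 6 region at 8627704 had 5 and 18. At 15059278 the log2 difference after that division was 1.72 (limma, Benjamini-Hochberg adjusted p = 0.0493).

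The largest decrease in ITGB4-high was on chromosome 11, 119438384 to 119439580, with a log2 difference of -3.29 ± 0.26 (SE, n = 2 per subline, limma adjusted p = 0.00167), with depth-scaled pileups of 4.12 ± 0.416 in ITGB4-low and 0.307 ± 0.0172 in ITGB4-high (SD, n = 2). Regions on the same chromosome at 119303152 and 119340913 had log2 differences of -2.95 and -2.89, and the ITGB4-low-specific region at 119351756 had -2.76. These 4 regions lay within 1 Mb of each other. The remaining regions with the largest decreases were on chromosome 11 at 101657465 (-3.26), chromosome 5 at 109624230 (-2.95) and chromosome 8 at 119647069 (-2.91). In the 6 regions with the largest decreases, unscaled ITGB4-high pileups were 5 to 13, where the lowest unfiltered pileups of those libraries were 5 and 4. In the 1 Mb of chromosome 11 from 119 Mb, the median local background over all unfiltered peaks, those in the regions included, was lower in ITGB4-high. It was 1.78 ± 0.223 times the genome mean against 3.61 ± 0.038 in ITGB4-low (SD, n = 2). Away from the regions, from 119 to 119.5 Mb, it was 1.02 and 1.45 in ITGB4-high and 2.41 and 2.78 in ITGB4-low. After division by the local background, the regions at 119438384, 119303152 and 119340913 had log2 differences of -1.23, -0.87 and -1.29 and no longer passed the threshold (limma, Benjamini-Hochberg adjusted p = 0.0545, 0.111 and 0.0676), while the region at 119351756 still did (-1.55, adjusted p = 0.0493).

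**Figure D2:**
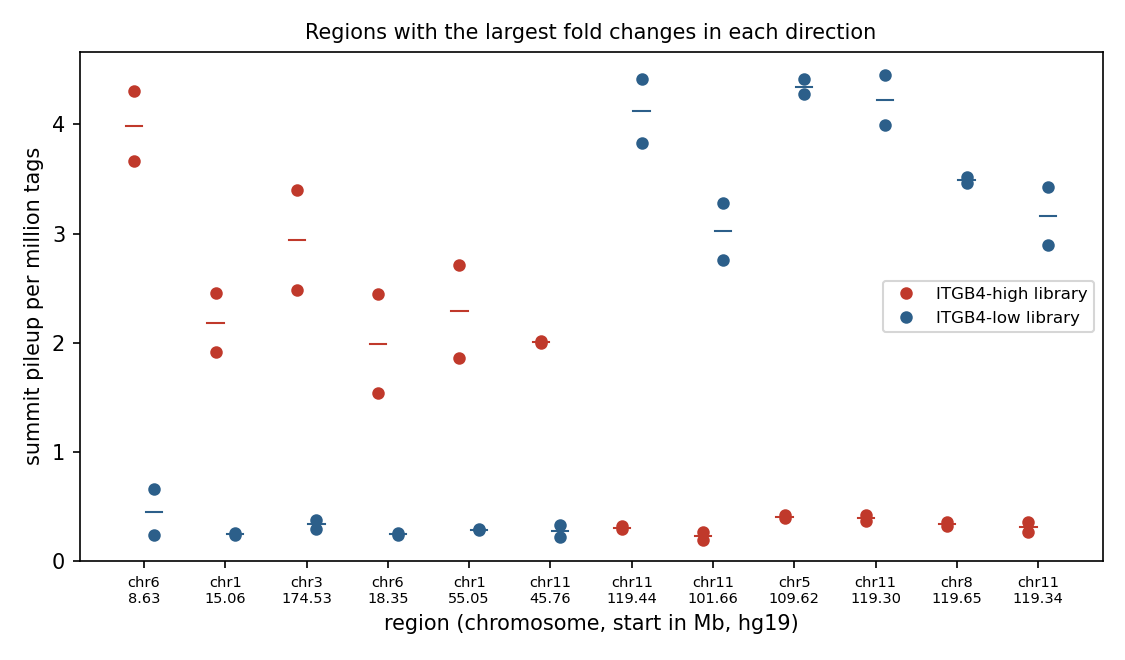
Summit pileup per 1000000 tags in each library (points) and the subline mean (lines, n = 2) for the 6 regions with the largest increases and the 6 with the largest decreases in ITGB4-high. In every region both libraries of 1 subline lay above both of the other.

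The 2 kinds of comparison overlapped, which is largely built in, since both draw on the same peaks of the same libraries. Of 789 tested ITGB4-high-specific regions, 613 were called higher, and of 5608 tested ITGB4-low-specific regions, 1443 were called lower and 2 higher. Another 2459 called regions were not group-specific. The groups did not overlap in 56.9% of tested regions, where chance gives 33.3%.

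Without ITGB4-low replicate 1 the test called 1024 regions higher and 611 lower, and without ITGB4-low replicate 2 it called 959 and 638. Scaled to tags without centring, all regions together were 0.46 lower in ITGB4-high (log2 difference of -0.46), and 1151 regions were called higher and 8408 lower. Divided by the local background, 149 were called higher and 62 lower. No region called both in the main test and in another setting differed in direction between them, with 205 to 4517 such shared calls per setting. All settings reused the same pileups and only shared calls were compared. A reversal could therefore hardly occur, and its absence says little about stability.

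**Figure D3:**
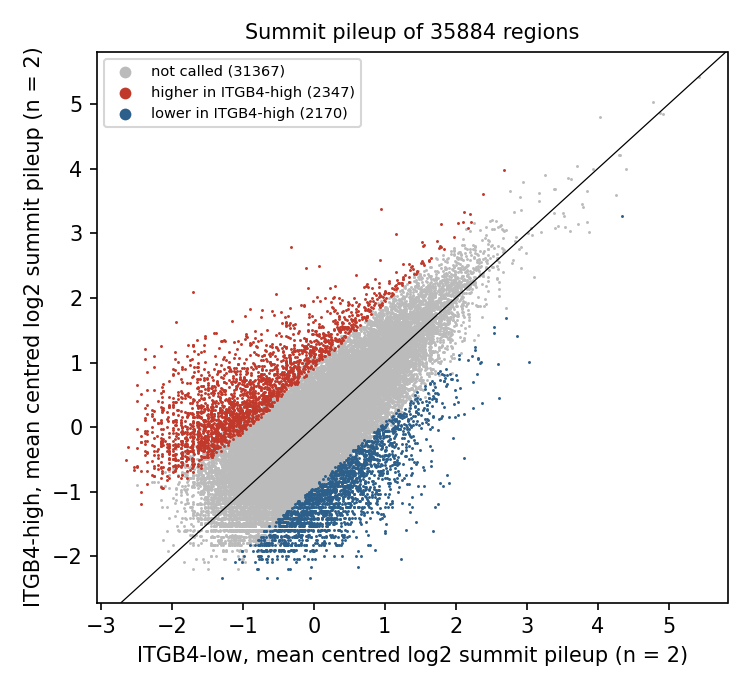
Each point is 1 of the 35884 tested regions, placed by its mean centred log2 summit pileup in ITGB4-low (horizontal axis) and ITGB4-high (vertical axis), with n = 2 libraries each. The 2347 regions called higher in ITGB4-high are red, the 2170 called lower are blue and the diagonal marks equal values.

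Changed regions were unevenly spread over the chromosomes. Chromosome 3 held 149 of the ITGB4-high-specific regions (13.1%) and 399 of the ITGB4-low-specific regions (5.64%), an odds ratio of 2.52 (Fisher's exact test, Benjamini-Hochberg adjusted p = 4.58e-16). Chromosomes 1, 4, 5, 6 and X also had larger shares of the ITGB4-high-specific regions, with odds ratios between 1.37 and 1.66 and adjusted p up to 0.0101. Smaller shares were found for chromosomes 2, 14, 16, 17, 18, 19, 20, 21 and 22. On chromosome 19 there was 1 ITGB4-high-specific region against 196 ITGB4-low-specific ones (Fisher's exact test, adjusted p = 8.57e-11), on chromosome 17 there were 5 against 210 (4.47e-08) and on chromosome 22 there were 0 against 102 (1.97e-06). With lists of equal length, chromosomes 4, 5 and 16 no longer passed the threshold and chromosome 15 newly passed it, with an odds ratio of 0.589 (Fisher's exact test, adjusted p = 0.0114), while the odds ratio of chromosome 3 was 3.10 (adjusted p = 7.68e-26).

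The shift on chromosome 3 lay mostly between 90 and 180 Mb. The 1436 regions tested there had a median log2 difference of 0.68 (SD over regions 0.71), 83.8% were above 0, and 381 were called higher and 27 lower. The medians of the 9 bins of 10 Mb ranged from 0.49 to 0.95, against 0.02 to 0.20 for the 9 bins from 0 to 90 Mb. Local background away from the regions (upper quartile per bin, median of the 9 bins) was 1.35 and 1.36 times the genome mean in ITGB4-high. In the ITGB4-low libraries it was 1.07 and 1.13 times. After centring within 10 Mb bins, 87 regions in this stretch were called higher and 94 lower, which is 12.6% of those tested there against 9.82% of all regions tested in that setting.

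On chromosome 11 the direction changed along the arm. Between 100 and 110 Mb the median log2 difference over 160 regions was 0.48, with 39 regions called higher and 6 lower. Between 110 and 130 Mb it was -0.43 over 330 regions, with 17 called higher and 102 lower. After centring within 10 Mb bins, 15 regions were called higher and 21 lower in the first stretch, and 32 and 49 in the second. Local background from 100 to 110 Mb was 1.40 and 1.57 times the genome mean in the ITGB4-high libraries and 1.45 and 1.49 in the ITGB4-low libraries, a log2 difference of 0.02, so it did not shift with the pileup over the whole bin. The 1 Mb windows used another measure, the median over all unfiltered peaks, those in the regions included. By that measure, background in the 1 Mb from 106 Mb was 3.12 ± 0.195 times the genome mean in ITGB4-high and 2.13 ± 0.045 in ITGB4-low. In the bins from 110 to 120 and from 120 to 130 Mb the log2 difference of the background away from the regions was -0.52 and -0.76. The median pileup differences in these bins were -0.15 and -0.56. From 130 to 140 Mb the pileup difference was -0.50 over 33 regions, beside -0.15 for the background. In the 1 Mb from 123 Mb the ratio was lowest among the 1 Mb windows listed. Background over all unfiltered peaks there was 1.38 ± 0.083 in ITGB4-high and 3.21 ± 0.025 in ITGB4-low (SD, n = 2). Chromosome 18 had a median of -0.33 over 725 regions, with 18 called higher and 91 lower. These stretches were chosen after the shifts were seen.

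**Figure D4:**
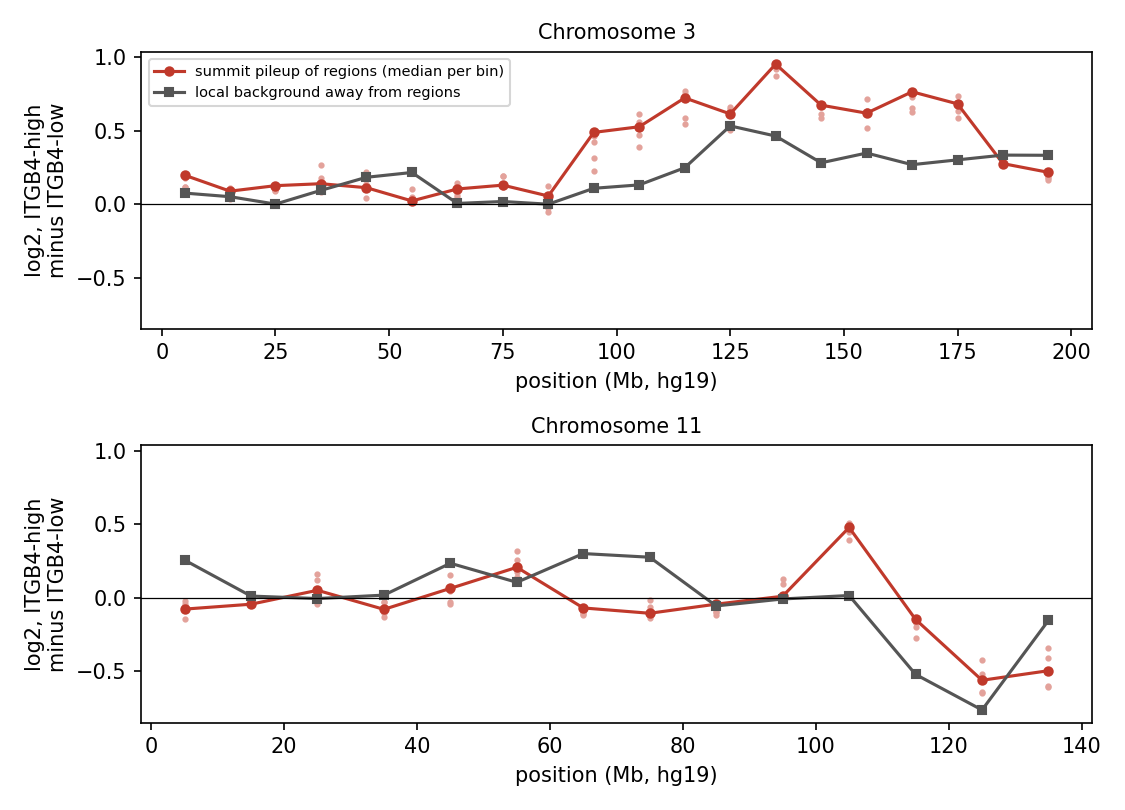
Difference between ITGB4-high and ITGB4-low (log2) along chromosomes 3 and 11 in bins of 10 Mb (hg19), for the summit pileup of regions (red line, median of the regions) and the local background away from them (grey line). Light points are the 4 pairs of 1 library from each subline, and both lines lie above 0 in the bins of chromosome 3 from 90 to 180 Mb.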

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

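Bin centring, division by local background and leaving out chromosomes 3, 11 and 18 were chosen after seeing the data. A stricter caller threshold kept both counts of group-specific regions within 1.5 times, and the other overlap rule changes nothing by construction, since each peak lies within its merged region. Lists of equal length gave 2242 ITGB4-high-specific and 2478 ITGB4-low-specific regions, and equal lengths bring these counts close together by construction. Requiring absence from the unfiltered lists gave 173 and 386. Requiring absence from the naive-overlap lists, given only for ITGB4-high, gave 1929 ITGB4-low-specific ones. That counts fall when absence is required is fixed by construction, but how far they fall is not. Leaving out 1 library gave 1525 to 3267 and 8497 to 15993, since fewer libraries had to meet the criteria. The mean Jaccard index between sublines rose from 0.397 to 0.440 with equal lists. In the summit pileup test, counts higher and lower were 1151 and 8408 when scaled to tags, where the shared shift is not removed. With missing pileups filled they were 2552 and 3835 among 26446 tested regions, those with filtered peaks in both libraries of a subline. The set of regions changed there together with the filling (the cause was not tested). For regions with mean pileup above the median the counts were 1529 and 1342, where fewer regions were tested. Leaving out 1 library gave 959 to 2025 higher and 611 to 2202 lower, each with a lone library assumed to vary like the others. Division by local background gave 149 and 62, and that background includes the peak's own tags. Without chromosomes 3, 11 and 18 the higher count was 1563, with fewer regions tested. The replicate block gave 2942 and 2800, and deviations of libraries with the same number correlated at 0.01, so the numbers were not taken as pairs. Quantile normalization and bin centring kept both counts within 1.5 times of the main ones. Of the comparisons of named regions with other settings, 238 kept their direction and side of the threshold and 10, all after division by local background, lost the threshold. The named regions were picked from these same libraries, and every setting reused their pileups. That most kept their side was therefore largely built in and says little about stability. The comparisons of gene lists, motifs and promoter shares, with their other settings, were not run. In the simulation with 4000 changes and 2 libraries per subline, the test called 37.4% of 2-fold changes, so most were missed there. The rate for the real pileups is not known.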

Other observations

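Very high local background, as the median over all unfiltered peaks in 1 Mb windows, was found on chromosome 8. From 128 to 129 Mb it was 22.5 ± 0.995 times the genome mean in ITGB4-high and 18.6 ± 0.352 in ITGB4-low, and from 129 to 130 Mb it was 27.0 ± 2.75 and 13.7 ± 1.29 (SD, n = 2). These 1 Mb windows were chosen after the values were seen.

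Except the test on shuffled positions in either direction, the tests that follow were chosen after the results were seen. That test too used calls after bin centring, a setting added after the data were seen. The higher pileup of chromosome 3 from 90 to 180 Mb was set against a difference in depth. In the pairs where the ITGB4-high library had fewer tags, the stretch was still higher in ITGB4-high, by at least 0.58 (median log2 difference). Within a subline it differed by at most 0.10. The shift was thus present whichever library was deeper. Each library had already been centred on its median and the stretch was picked for its shift. The comparison could therefore hardly have come out otherwise, and it does not decide on depth. Local background was higher in both ITGB4-high than in both ITGB4-low libraries in 9 of 9 bins, as was the case in 104 of 295 bins genome-wide (differences above 0.001 in log2), which is consistent with more copies of this DNA in ITGB4-high cells. The size of the background difference followed that of the pileup only in part. Medians of the bins were 0.05 for background beside 0.11 for pileup from 0 to 90 Mb, and 0.28 beside 0.67 from 90 to 180 Mb. From 180 to 200 Mb, however, the background difference was 0.33 (2 of 2 bins higher) beside a pileup difference of 0.25. From 0 to 90 Mb, 4 of 9 bins had a higher background. Background is not input DNA, and weak accessibility spread over the stretch could raise it as well, so copy number remains a hypothesis.

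ITGB4-low-specific regions outnumbered ITGB4-high-specific ones by a ratio of 6.21, and the ratio of 1.11 with lists of equal length does not decide, since equal lengths bring the counts close together. It was 2.23 with absence from the unfiltered lists, and leaving out 1 library moved it to between 2.60 (without ITGB4-high replicate 2) and 10.5 (without ITGB4-low replicate 1). Whether fewer tags played a part cannot be told from these libraries: the deepest, ITGB4-high replicate 1, had 22453 filtered peaks, fewer than either ITGB4-low library, while ITGB4-high replicate 2 had both the fewest tags, 18822664, and the shortest list, 18177. Why the lists differ in length was not tested, and a difference between the sublines stays open.

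Chromosomes 2, 14, 16, 17, 18, 19, 20, 21 and 22, which held smaller shares of ITGB4-high-specific regions, had a lower median pileup in ITGB4-high in 70 of 78 bins. Fewer DNA copies could lower the background too. Both ITGB4-high libraries lay below both ITGB4-low libraries in 29.5% of these bins, against 16.9% of all bins genome-wide. They lay above them in 27 of 78, against 104 of 295 genome-wide. Copy number over these chromosomes as a set stays open. The bins with lower background were on chromosomes 2 (12 of 25), 14 (3 of 9), 18 (6 of 8) and 21 (2 of 4), and chromosomes 16, 17, 19, 20 and 22 had none. On these 5 chromosomes the background was instead higher in both ITGB4-high libraries in 20 of 32 bins, among them 5 of 5 on chromosome 19 and 7 of 9 on chromosome 16, the opposite of what a loss would give. Sequence composition and a difference between the sublines were not tested.

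Changed regions after bin centring were tested for clustering in windows of 500 kb by 1000 shuffles of the calls within chromosomes. In either direction the fullest window held 10 regions, against a median of 5 in the shuffles (p = 0.001 by permutation, the smallest they can give). The prediction for either direction was written beforehand, but its value was computed in this form only after the values of the separate directions had been seen. That window was on chromosome 11 from 119 to 119.5 Mb, where 10 of 16 tested regions were lower in ITGB4-high, and the window from 118.5 to 119 Mb also held 10. Regions higher in ITGB4-high showed no such excess, with at most 5 per window (p = 0.577 by permutation), nor did lower regions away from chromosome 11, with at most 6 (p = 0.108). Both windows with 10 regions lay where the local background was also lower in ITGB4-high, and a copy-number difference smaller than a 10 Mb bin could contribute, which was not tested.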
